A study of Picosynechococcus sp. PCC 7002 with 12 samples.

How the data were processed

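RNA from 12 cultures of Synechococcus sp. PCC 7002 (strain BMB04) was sequenced, 3 cultures at each of 4 iron levels. Per the labels' protocols, iron was buffered with EDTA at a total of 200 nM for 10.9 nM of dissolved inorganic iron, 20 nM for 0.41 nM, 2 nM for 0.04 nM and 0.6 nM for 0.003 nM, and the 3 cultures of a level are biological replicates. Per the labels' protocols, ribosomal RNA was depleted with capture oligonucleotides and libraries were made with a stranded kit and sequenced as single reads. Reads were checked with FastQC, aligned with TopHat 2.0 to the Cyanobase genome of this strain and counted per gene with HTSeq 0.5.3, per the labels' protocols and the submitters' processing notes. How the counting treated strand and how the counts were scaled are not given in the sources used here, so overlapping and antisense genes, and genes with near-identical copies, could share reads.

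The deposited table holds 3171 locus tags in 12 columns, 1 per library, and its name calls the values normalized counts in CPM. The column totals ran from 710329 to 1327870 and so are not plain CPM. They are treated here as a normalized signal deposited by the authors, that is, CPM on an effective library size rather than on the plain total. Groups were taken from the sample titles and columns were matched to samples by their labels, with 1 exception. For severe replicate C the label naming its column ended in A, while the column itself ended in C. That column was assigned from the sample title and the treatment protocol, which both give replicate C. The planned test assumed plain CPM, and the same test on the log scale was kept for this signal. No tag was listed with fewer than 6 libraries at 0.5 or more.

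Low values in each library were whole multiples of what 1 read is worth. Over the 12 libraries, 7190 values lay above 0 and under 12, and 100% of them in every library came within 0.1 read of a whole number, which gave 3925987 to 6493218 recovered reads per library. In 6 libraries the smallest value was 1 read and in the other 6 it was 2 or 3 reads, so for those 6 the step rests on the search over step sizes. On simulated reads, the step search gave the true whole count for at least 99.8% of the tags in each library. This is a share of tags, not of reads. Pairs of replicates of a level differed by a chi-square of 17.1 to 70.5 per degree of freedom, far above the counting noise of 1, so no library was a repeat of another.

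Tags with a mean of at least 1 over the 12 libraries were tested, which removed 19 and left 3152. The values were tested as log2(value + 1) in limma 3.58.1 (R 4.3.3) with 1 mean per iron level in a single fit of all 12 libraries, empirical Bayes with a trend, 8 residual degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment within each comparison, with calls at an adjusted p under 0.05. The comparisons were each limited level against replete, the 2 steps between neighbouring levels and an F test over the 3 contrasts with replete. The comparisons, the alternatives planned for them and the rule for the tags named were fixed before the data were examined.

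Of the 3171 locus tags, 0 matched an identifier in the RefSeq gene table used here, which lists 3279 genes on 7 replicons. The 31 gene lists fixed in advance (iron transport, photosystems, pigments, electron carriers, stress defence and others) therefore could not be tested and are not reported here. The rule for named tags was then its stated fallback: for each comparison the 2 largest rises and the 2 largest falls among tags past the threshold with a mean of at least 10 and no overlap between the libraries of the 2 levels. SYNPCC7002_A0263 and the values of SYNPCC7002_A0983 and SYNPCC7002_A1224 outside the comparison that named them, and the ends of runs of tags, were chosen after their values were seen.

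Tags were grouped by the letter of the identifier, and the 7 series were tested with camera on the same fit with a preset correlation of 0.01, with camera with an estimated correlation, and with fry, with Benjamini-Hochberg adjustment over the 35 tests of 7 series in 5 comparisons. Series were also set against 10000 random lists of chromosomal tags of the same size and mean expression. Runs of at least 4 consecutive tag numbers called the same way and at least 2-fold were counted and compared with 1000 shuffles of the tags within their series. Overlap between comparisons that share the replete libraries was set beside 100 simulations of unchanged groups. These groupings of tags were chosen after the files were seen.

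The counts of calls were recomputed under 24 planned and 3 added alternatives: 2 other pseudocounts, no filter and a filter at a mean of 10, median-of-ratios and quantile rescaling, removal of the 10 most abundant tags, limma's weights for each library, the replicate letter as a block, each library left out in turn, a fit on the compared pair alone, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads of all 12 libraries, and, added after seeing the data, rescaling all libraries to the same total, thinning to the shallowest effective depth and leaving out the 3 shallowest libraries of their levels together. The 3 shallowest libraries, here and below, are replicate A of severe, mild and replete, each the shallowest of its level. They are not the 3 shallowest of all 12, since replete replicate B was shallower than severe replicate A. As they share a letter, leaving them out does not vary depth alone. Against 2021 calls in limma for severe limitation against replete, edgeR called 2033 and DESeq2 1997, with 1542 and 1553 for strong against replete and 1180 and 1194 for mild against replete. For strong against mild they called 566 and 654, and for severe against strong 1285 and 1279.

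On simulated counts for severe limitation against replete, with 200 of 3152 tags changed at the common dispersion of 0.0191, limma recovered 53.7% of tags changed 1.5-fold, 95.5% of those changed 2-fold and 98.5% of those changed 4-fold, and 4.07% of its calls were on unchanged tags. In this simulation changes of 1.5-fold were thus often missed. It gave 172 calls in limma where the data gave 2021, so the adjusted threshold was looser in the data. The recovered shares and the share of false calls therefore need not hold for the data. Replicate letters were checked for pairing by correlating deviations from the group means. In the added contrast of severe with mild limitation all 3 same-letter pairs correlated above 0.1 (A 0.56, B 0.30, C 0.33), each the highest of that severe library with any mild library, though the labels name no shared batch. With the letter as a block that contrast called 1742 tags in place of 1699, and in a fit of those 6 libraries alone 1999 in place of 1656. Figures were drawn with matplotlib 3.10.9.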

Results

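The transcriptome of the unicellular marine cyanobacterium Synechococcus sp. PCC 7002 (Picosynechococcus), in its bioreporter strain BMB04, was measured by RNA sequencing at 4 levels of dissolved inorganic iron. The control was iron replete, at 10.9 nM inorganic iron. The limited cultures held 0.41 nM (mild limitation), 0.04 nM (strong limitation) and 0.003 nM (severe limitation). Each level had 3 biological replicates, for 12 libraries in all, from cultures acclimated to their iron level and harvested in exponential growth. Values were available for 3171 locus tags, of which 3152 were tested. The reads recovered per library ran from 3925987 to 5267522 in the replete group, 4400055 to 5849538 in mild, 6117214 to 6493218 in strong and 5450793 to 6277014 in severe limitation, so depth was not equal between the groups. The files do not pair the locus tags with gene names, so tags are given by their identifiers, and what their products do is not described here. Levels below are normalised read counts on the CPM scale, as mean ± SD with n = 3. Log2 fold changes are on the log2(value + 1) scale, which understates the change of low tags, and adjusted p-values are from limma with Benjamini-Hochberg adjustment.

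Severe limitation against the replete control asked how far the transcriptome moved at the lowest iron level. SYNPCC7002_G0020 had the largest rise, from 21.0 ± 4.04 in replete to 5534 ± 1638 in severe limitation (log2 fold change 7.95, SE 0.25, limma adjusted p = 7.33e-13). SYNPCC7002_A2657 rose from 3.44 ± 2.15 to 873.7 ± 35.6 (log2 fold change 7.73, SE 0.23), and its replete level rested on 39 reads over 3 libraries. SYNPCC7002_A0250 had the largest fall, from 4753 ± 1321 to 107.0 ± 6.70 (log2 fold change -5.43, SE 0.20), followed by SYNPCC7002_A1443, from 1290 ± 133 to 51.7 ± 8.70 (log2 fold change -4.62, SE 0.16). In total 2021 of 3152 tags passed an adjusted p of 0.05, or 64.1%, with 1043 higher and 978 lower. At least 2-fold changes were seen for 402 of the higher and 390 of the lower tags, and at least 10-fold changes for 36 and 19. The split of rises and falls depended on the scaling. It was 977 to 1039 with median-of-ratios rescaling and 915 to 1021 with quantile normalization. With all libraries rescaled to the same total, an alternative chosen after seeing the data, the median log2 fold change over all tags moved from 0.05 to 0.76, and 2065 tags were called higher and 309 lower, of which 1214 and 102 differed at least 2-fold. After leaving out the 10 most abundant tags and rescaling, the median was 0.35 and the split 1473 to 624.

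**Figure D1:**
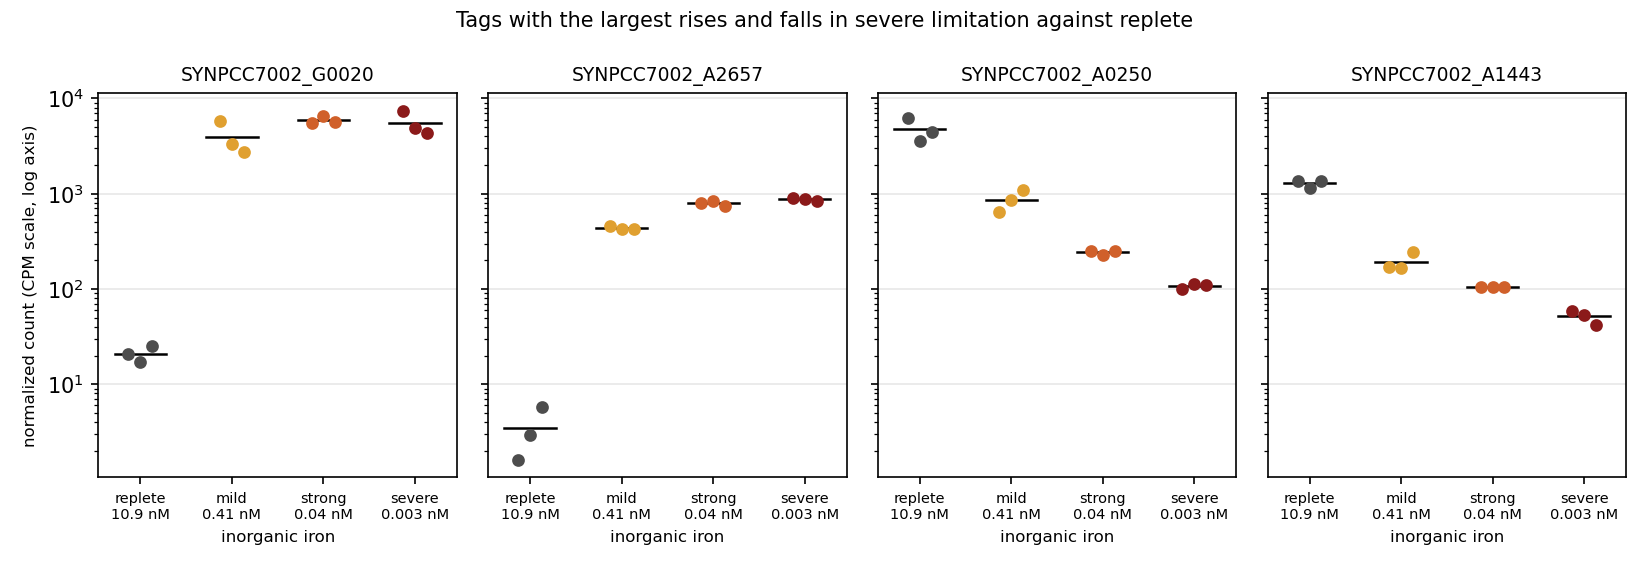
Normalised read count (log axis, CPM scale) in each of the 12 libraries, by inorganic iron level, for the 2 tags with the largest rise and the 2 with the largest fall in severe limitation; points are libraries and bars are group means (n = 3). SYNPCC7002_G0020 stood at 21.0 in replete and at 3948, 5909 and 5534 in mild, strong and severe limitation, while SYNPCC7002_A0250 went from 4753 in replete to 862.4, 242.6 and 107.0.

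Strong limitation against replete repeated the comparison at 0.04 nM. The largest rises were those of SYNPCC7002_G0020, at 5909 ± 569 (log2 fold change 8.08, SE 0.25), and of SYNPCC7002_G0023, at 8329 ± 915 against 34.2 ± 11.7 in replete (log2 fold change 7.93, SE 0.24). SYNPCC7002_A0893 fell to 14.5 ± 1.94 (log2 fold change -4.53, SE 0.41, limma adjusted p = 5.95e-07; -3.80 without replete replicate A). Its replete libraries differed widely, at 978.4, 182.1 and 250.8 in replicates A, B and C. SYNPCC7002_A0250 fell to 242.6 ± 14.6 (log2 fold change -4.25, SE 0.20). In limma, 1561 tags passed, 790 higher and 771 lower, of which 245 and 181 differed at least 2-fold. With all libraries rescaled to the same total the median log2 fold change was 0.42 in place of 0.02, and the split was 1509 higher to 275 lower, with 555 and 73 at least 2-fold.

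Mild limitation against replete tested the smallest reduction in iron. SYNPCC7002_G0020 stood at 3948 ± 1602 (log2 fold change 7.43, SE 0.25) and SYNPCC7002_G0023 at 5976 ± 1632 (log2 fold change 7.42, SE 0.24). The largest falls were those of SYNPCC7002_A0893, to 19.4 ± 3.12 (log2 fold change -4.14, SE 0.41; -3.41 without replete replicate A), and of SYNPCC7002_A1735, from 136.6 ± 41.6 to 7.89 ± 5.76 (log2 fold change -4.09, SE 0.35, limma adjusted p = 3.55e-07). In limma, 1200 tags passed, 614 higher and 586 lower, with 178 and 92 at least 2-fold. A fit on the 6 libraries of the pair alone called 799. With all libraries rescaled to the same total the median log2 fold change was 0.26 in place of 0.02, and the split was 1006 higher to 227 lower, with 290 and 59 at least 2-fold.

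**Figure D2:**
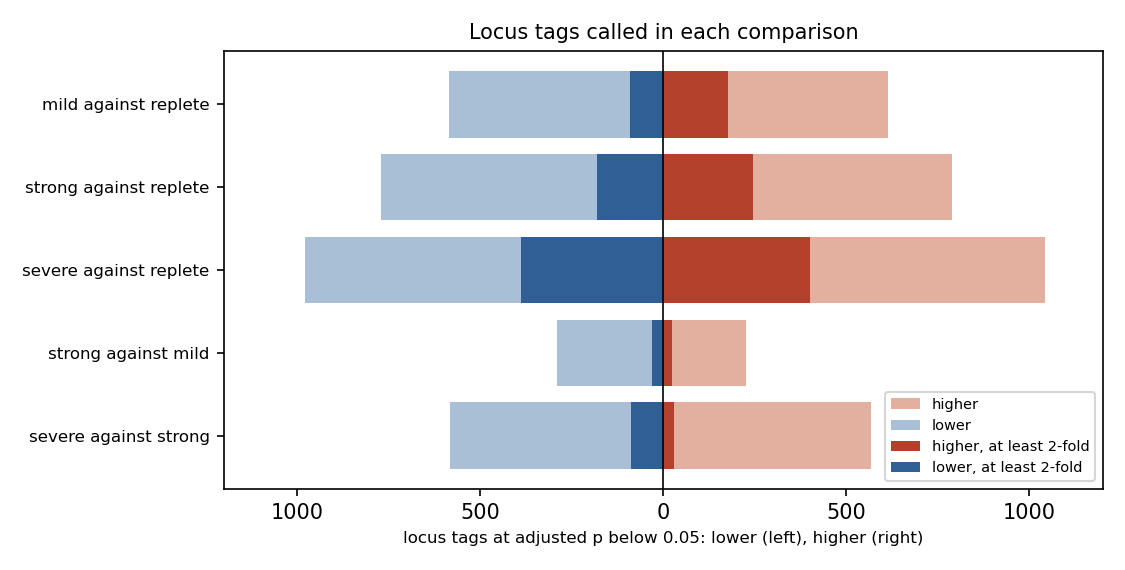
Number of locus tags past a limma adjusted p of 0.05 in each comparison, higher to the right and lower to the left of 0 on the x axis; dark parts are tags that differed at least 2-fold. Against replete the count goes from 1200 in mild to 1561 in strong and 2021 in severe limitation. The split is also near even with median-of-ratios rescaling (588 higher and 607 lower in mild, 774 and 799 in strong, 977 and 1039 in severe limitation). That rescaling centres the log2 fold changes near 0, so it cannot show that the balance holds. On the deposited scale their median was also near 0 (0.02 in mild and strong, 0.05 in severe limitation). The near-even split there is thus tied to the scaling as well. Rescaling all libraries to the same total gives 1006 higher and 227 lower tags in mild, 1509 and 275 in strong, and 2065 and 309 in severe limitation.

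The 2 steps between neighbouring iron levels asked what changed within the limited range. From mild to strong limitation, SYNPCC7002_A1735 rose from 7.89 ± 5.76 to 40.1 ± 9.71 (log2 fold change 2.36, SE 0.35, limma adjusted p = 7.48e-04), and SYNPCC7002_A1733 from 6.89 ± 3.31 to 24.9 ± 4.33 (log2 fold change 1.78, SE 0.26). Both stayed under their replete means of 136.6 ± 41.6 and 65.6 ± 17.4. SYNPCC7002_A0250 fell further, from 862.4 ± 224 to 242.6 ± 14.6 (log2 fold change -1.79, SE 0.20), and SYNPCC7002_F0053 fell from 17.5 ± 4.04 to 4.50 ± 1.15 (log2 fold change -1.75, SE 0.20). This step had 516 tags past the threshold in limma, 225 higher and 291 lower, 54 of them at least 2-fold. With all libraries rescaled to the same total the split was 397 to 117 and the median log2 fold change 0.17 in place of 0.02. After leaving out the 10 most abundant tags and rescaling, 232 were higher and 198 lower. The count fell to 254, 260 and 237 without strong replicate A, B or C, and 828 tags passed with a weight for each library.

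From strong to severe limitation, SYNPCC7002_A1224 showed the largest fall, from 785.5 ± 164 to 72.4 ± 16.8 (log2 fold change -3.42, SE 0.21, limma adjusted p = 2.71e-07). SYNPCC7002_A0983 fell from 33654 ± 422 to 8185 ± 1803 (log2 fold change -2.06, SE 0.24). The largest rises were smaller, with SYNPCC7002_G0083 going from 46.8 ± 3.41 to 156.8 ± 35.4 (log2 fold change 1.70, SE 0.24) and SYNPCC7002_A2287 from 15.0 ± 4.24 to 40.3 ± 11.6 (log2 fold change 1.36, SE 0.28). SYNPCC7002_A2287 stayed under its replete mean of 83.1 ± 21.4, while SYNPCC7002_G0083 stood at 3.08 ± 1.02 in replete. In limma 1152 tags passed, 568 higher and 584 lower, but among the 119 that differed at least 2-fold only 30 were higher and 89 lower. This 2-fold split was 48 to 131 without severe replicate A and 14 to 64 with a pseudocount of 5. It was 50 to 131 without the 3 shallowest libraries of their levels together (replicate A of severe, mild and replete). It turned to 128 higher and 36 lower without the 10 most abundant tags and rescaled, and to 181 and 32 with all libraries at the same total. With all libraries rescaled to the same total, 1222 tags were higher and 237 lower, and the median log2 fold change was 0.33 in place of 0.02. Without the 10 most abundant tags and rescaled, the split was 1058 to 292 and the median log2 fold change 0.26. The count fell to 712 without severe replicate B and 714 without strong replicate B. It rose to 1673 in a fit on the pair alone and to 2009 with a weight for each library.

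Over the whole iron series, limma's F test called 2381 of 3152 tags, or 75.5%. The limited levels shared many of their calls against replete: 393 tags were higher and 362 lower at all 3 levels. Severe and mild limitation had 419 higher and 386 lower tags in common, where independent lists of those sizes would share 203.2 and 181.8, and 76 tags were called in opposite directions. Across tags, which are not independent replicates, the log2 fold changes of severe and mild limitation correlated at r = 0.77. Unchanged groups simulated against the same 3 replete libraries gave r = 0.50, with covariances of 0.70 observed and 0.0162 simulated. The simulations gave a mean of 0 tags called the same way in both. Unchanged groups are seldom called, and a shared control of equal size alone gives r near 0.50, so neither value tests the overlap. The 3 replete libraries were not split, since that would leave 1 on a side, so part of the excess in correlation and overlap may come from the shared controls, while the difference in covariance, 0.68, estimates the shared effect. Severe and strong limitation had r = 0.90 and strong and mild r = 0.91, against 0.50 in both simulations.

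The 2 tags with the highest mean over the 12 libraries were singled out after their values were seen. They ranked 1 and 2 by mean level in replete and mild limitation, but 1 and 3 in strong and 4 and 12 in severe limitation. SYNPCC7002_A0263 stood at 148893 ± 22117 in replete, 71733 ± 14998 in mild, 40554 ± 4826 in strong and 14823 ± 2425 in severe limitation, and SYNPCC7002_A0983 at 159070 ± 29775, 69460 ± 22287, 33654 ± 422 and 8185 ± 1803. Both fell past limma's threshold in all 5 comparisons. For SYNPCC7002_A0263 the step from mild to strong limitation no longer passed without strong replicate A (log2 fold change -0.76 in place of -0.81, limma adjusted p = 0.0770), strong replicate C (-0.76, 0.0897) or mild replicate A (-0.65, 0.0624). Quantile normalization, which gives tags of the same rank the same value, ended the calls of both tags in strong and mild limitation against replete and in strong against mild. Under it the log2 fold changes of SYNPCC7002_A0263 there were 0, and those of SYNPCC7002_A0983 were 0 in mild limitation and -0.49 in the other 2 (adjusted p = 0.0662 against replete and 0.12 against mild). It also moved severe against replete from -3.33 to -1.21 for SYNPCC7002_A0263 and from -4.29 to -2.52 for SYNPCC7002_A0983, both still called. Together they made up 24.1% ± 1.3 of the summed signal in replete, 13.1% ± 2.14 in mild, 7.76% ± 0.12 in strong and 2.99% ± 0.36 in severe limitation (n = 3). The summed signal itself was 1279332 ± 42467 in replete, 1071147 ± 108655 in mild, 956664 ± 57152 in strong and 768216 ± 62569 in severe limitation.

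The letter in a locus tag of this organism names the replicon, with A for the chromosome and B to G for plasmids. Because names could not be attached, tags were also grouped by this letter, a choice made after the files were seen. Series G held 154 tested tags, of which 60 were higher and 48 lower in severe limitation, with a median log2 fold change of 0.06. Its camera test in severe limitation did not pass (adjusted p = 0.14), but did among tags with a mean of at least 10 (median 0.13, adjusted p = 0.0253). That median was -0.20 with quantile normalization, -0.0032 without replete replicate A and -0.01 without the 3 shallowest libraries together, so its direction was not stable. Its share of the summed signal was 1.02% ± 0.12 in replete, 4.66% ± 0.43 in mild, 6.74% ± 0.11 in strong and 7.40% ± 0.64 in severe limitation (n = 3). The 11 tags from SYNPCC7002_G0016 to SYNPCC7002_G0026 carried most of this rise, at 0.02% ± 0.0032, 2.82% ± 0.40, 4.60% ± 0.13 and 5.13% ± 0.63, while the other 143 tags went from 1.00% ± 0.12 to 1.85% ± 0.05, 2.14% ± 0.03 and 2.27% ± 0.05. In mild limitation 70 were higher and 13 lower (median 0.28, camera adjusted p = 7.28e-09 with a preset correlation of 0.01, adjusted p = 0.10 with an estimated correlation), and in strong limitation 69 were higher and 23 lower (median 0.28, camera adjusted p = 3.66e-06, adjusted p = 0.21 with an estimated correlation). Series E held 37 tested tags. Of these, 21 were higher and 1 lower in mild, 28 and 1 in strong, and 25 and 5 in severe limitation, with medians of 0.64, 0.94 and 0.93. Camera called series E at all 3 levels with the preset correlation (adjusted p = 5.79e-05, 2.22e-07 and 4.52e-04), and the adjusted p was 0.38, 0.29 and 0.41 with an estimated correlation. In fry, which tests whether the tags of a series move on balance one way without comparing them with other tags, series E had adjusted p-values of 3.72e-03, 1.85e-04 and 3.77e-04. This was not particular to series E. Fry in severe limitation also called series G (adjusted p = 6.69e-06), C (3.25e-05), B (3.71e-04), D (4.26e-03) and F (8.58e-03), but not A (0.48). Series B, C and G passed fry in mild and strong limitation as well, and series A, D and F did not. Series C, of 16 tags, had medians of 0.56, 0.50 and 0.63 in mild, strong and severe limitation (camera adjusted p = 2.92e-03, 2.13e-03 and 0.0386; adjusted p = 0.21, 0.21 and 0.32 with an estimated correlation). Its call in severe limitation was lost in 5 of 24 alternatives: without severe replicate A (adjusted p = 0.0533), without mild replicate A (0.0535), without the 3 shallowest libraries together (0.0965), with weights for each library (0.0738) and with all libraries rescaled to the same total (0.0738). Series B, of 3 tags, had medians of 0.97, 1.3 and 1.1 and camera adjusted p-values of 0.0227, 0.0227 and 0.17, of which the first 2 became adjusted p = 0.21 with an estimated correlation. The call of series B in mild limitation was lost without mild replicate A (adjusted p = 0.0535) and without the 3 shallowest libraries together (0.0906).

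Series F and D moved in the step from strong to severe limitation. Of the 98 tested tags of series F, 1 was higher and 44 were lower in severe than in strong limitation, with a median log2 fold change of -0.51 (camera adjusted p = 7.12e-08, adjusted p = 0.21 with an estimated correlation). Of the 26 in series D, 0 were higher and 9 lower, with a median of -0.40 (camera adjusted p = 5.19e-03, adjusted p = 0.30 with an estimated correlation). Series G had 16 higher and 40 lower in this step and a median of -0.26 (camera adjusted p = 1.13e-03, adjusted p = 0.30 with an estimated correlation). In fry for this step the adjusted p was 1.13e-03 for F, 4.26e-03 for D, 2.70e-03 for G and 0.0399 for B. Series A, C and E did not pass fry there. With all libraries rescaled to the same total the series G median in this step was 0.04, while series A stood at 0.37, so relative to series A it was -0.33. Against replete, series F and D did not pass the camera test in severe limitation (medians -0.13 and -0.40, adjusted p = 0.11 and 0.0667), and both medians turned positive, to 0.49 and 0.29, with all libraries rescaled to the same total. The median of series F was also positive, at 0.11, without the 10 most abundant tags. Each of these series passed as lower than the other tags in 8 of 24 alternatives, so neither the call nor the median was stable. Among tags with a mean of at least 10 the medians were -0.59 for F (adjusted p = 0.0074) and -0.66 for D (0.0338). With quantile normalization they were -0.35 (0.0104) and -0.63 (0.0074), and with weights for each library -0.33 (0.0347) and -0.41 (0.0178). Without severe replicate A they were -0.31 and -0.36 (adjusted p = 0.0438 for both), without replete replicate A -0.36 (0.0252) and -0.45 (0.0358), and without the 3 shallowest libraries together -0.45 (0.00982) and -0.35 (0.0217). The other 2 were the rescalings: relative to series A, the medians with all libraries at the same total were -0.27 and -0.46. In mild and strong limitation the medians were 0.15 and 0.16 for series F (camera adjusted p = 0.14 and 0.32) and -0.02 and -0.05 for series D (adjusted p = 0.81 for both). Series F passed in mild limitation without mild replicate B (adjusted p = 0.0475) and without replete replicate C (median 0.25, adjusted p = 0.0193), but its median there was 0.02 without replete replicate A and -0.01 without the 3 shallowest libraries together. In strong limitation it was 0.05 without replete replicate A and 0.27 without replete replicate C. The chromosomal series A had medians of -0.0047, -0.0075 and 0.05 in mild, strong and severe limitation. Camera, which compares a series with all other tags, placed it lower in mild and strong limitation (adjusted p = 1.34e-07 and 5.05e-06, adjusted p = 2.23e-03 for both with an estimated correlation), although its mean in mild limitation was above 0. In severe against strong limitation camera placed series A higher (median 0.06, adjusted p = 1.77e-06, adjusted p = 2.23e-03 with an estimated correlation). Series A holds 2818 of the 3152 tested tags, so these calls mirror the plasmid tags and do not show a shift of the chromosome. The estimated correlation was that within series A (0.0043), not that within the plasmid series (0.06 in G to 0.29 in E). The adjusted p-values for series A may therefore be too small.

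**Figure D3:**
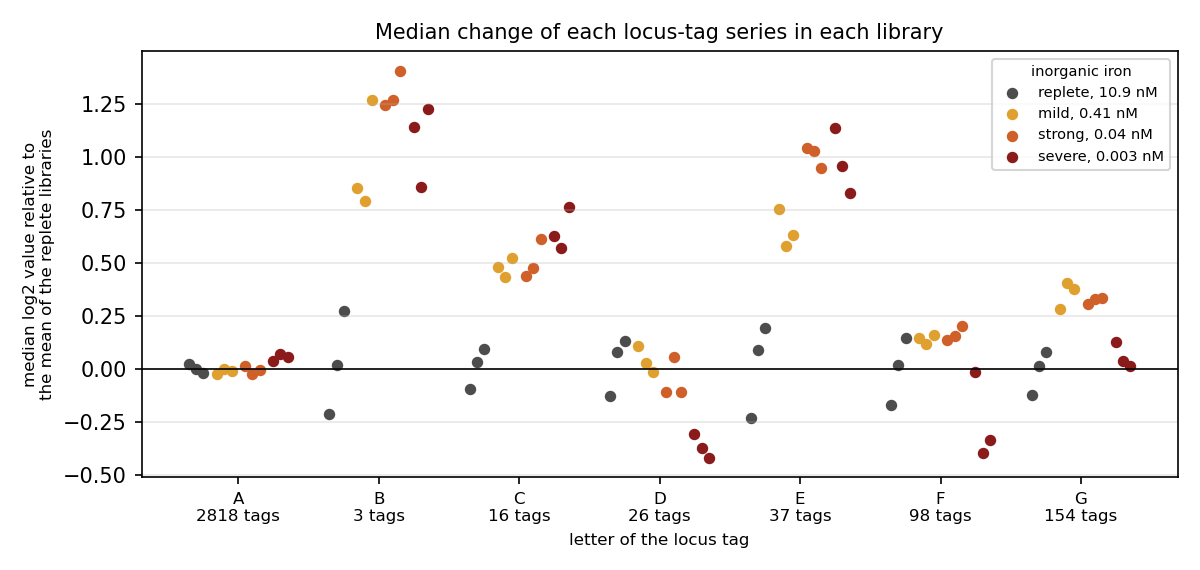
Median over the tags of each series of the log2 value relative to the mean of the replete libraries (y axis), for each of the 12 libraries, by the letter of the locus tag (x axis); colours give the iron level. All limited libraries of series E lie above its replete libraries, between 0.58 and 1.13, and the severe libraries of series F lie at -0.01, -0.40 and -0.33; with all libraries rescaled to the same total, the series F median in severe limitation against replete is 0.49.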

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

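The contrast of severe with mild limitation and the tag named here were chosen after the result was seen. In 76 tags the call against replete went one way in mild limitation and the other way in severe limitation. The direct contrast of severe with mild limitation in limma called all 76, which their selection fixes, since both calls rest on the same replete libraries and the same standard error, and so it adds no evidence. The number was 50 without severe replicate B, 46 without replete replicate B and 162 with weights for each library. Of the 76, 40 were higher in mild and lower in severe limitation, and 36 were lower in mild and higher in severe. Series A held 72 of them and series G 4. The largest such change among tags with a mean of at least 10 was that of SYNPCC7002_A1224, at 330.8 ± 59.9 in replete, 912.3 ± 229 in mild, 785.5 ± 164 in strong and 72.4 ± 16.8 in severe limitation (n = 3 each). Its log2 fold changes against replete were 1.45 (SE 0.21, limma adjusted p = 9.98e-05) in mild and -2.18 (SE 0.21, limma adjusted p = 5.73e-07) in severe limitation. They ran from 1.25 to 1.71 and from -2.36 to -1.45 over the 27 alternatives. Of the 1200 tags called in mild limitation, 355 moved back past the threshold from mild to severe limitation and 324 passed it moving further the same way, or 235 and 531 with all libraries rescaled to the same total. With the replicate block these were 368 and 336, and 80 tags went opposite ways. The mild libraries enter both the choice of these tags and the second contrast, with opposite sign. Noise in them therefore favours moving back, so the 2 counts do not weigh return against further change.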

How the results depend on the processing

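Of 881 values of tags followed by name under the 27 alternatives, 872 kept direction and call. These tags were mostly named for large changes, so this does not speak for tags with smaller ones. The other 9 are of SYNPCC7002_A0263 and SYNPCC7002_A0983, 6 of them with quantile normalization. The total calls against replete stayed within 1.5 times under all of them except 799 for mild against replete in a fit on the pair alone, but their split by direction and the 2-fold count in severe limitation (1316 in place of 792 at the same total) did not. Similar totals also hid a turnover of tags. At the same total, 1352 of the 2021 main calls in severe, 1065 of 1561 in strong and 841 of 1200 in mild limitation were shared. In severe limitation 43 tags were called in the opposite direction. Rescaling all libraries to the same total, thinning and leaving out the 3 shallowest libraries together were chosen after seeing the data. With weights for each library, 828 tags passed in strong against mild and 2009 in severe against strong. Leaving out replicate A of severe, mild and replete together gave 887 in strong against mild. The cause was not tested. Leaving out 1 library gave 1800 to 2084 calls for severe, 1273 to 1648 for strong and 990 to 1271 for mild against replete, 237 to 720 for strong against mild, 712 to 1360 for severe against strong and 2124 to 2478 in the F test. The lowest count came without strong replicate C for strong against mild (254 and 260 without strong replicate A and B) and without severe replicate B for severe against strong (714 without strong replicate B). The highest count of both steps came without replete replicate A, a library of neither comparison. For severe and strong against replete it came without mild replicate A, again a library of neither. Such libraries enter through the standard error that the fit shares over all levels. Some series medians reversed. Series F in severe against replete was 0.11 without the 10 most abundant tags and 0.49 with libraries rescaled to the same total, which also gave 0.29 for series D there and 0.0419 for series G in severe against strong. These rescalings also raised the median of all tags, to 0.35 and 0.76 in severe against replete. In none of the 5 planned comparisons did all 3 same-letter pairs have deviations correlated above 0.1. In strong against replete 2 of them did (A 0.38, B 0.13, with C at 0.07), so partial pairing there is not excluded. Over all 6 pairs of levels, r ran from -0.25 to 0.56, and 0 libraries correlated best with their own letter in every other group. With the replicate block, 2051, 1582, 1223, 560 and 1183 tags passed in severe, strong and mild against replete, strong against mild and severe against strong. Leaving out ribosomal and transfer RNA genes and the alternatives for the gene lists were not run. Thinned to equal effective depth, 1947, 1434 and 1050 tags passed in severe, strong and mild against replete, so depth limits the counts more in mild limitation.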

Other observations

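In this part the tests of runs of tags, of the share of change reached in mild limitation and of scaling relative to series A were chosen after the result was seen. Neighbouring tags changed together. In severe limitation against replete, 14 runs of at least 4 consecutive tag numbers were higher and at least 2-fold, holding 83 tags, where 1000 shuffles within series gave 1.80 runs on average and at most 7. A further 9 runs were lower, holding 48 tags, against 0.74 on average and at most 4. The longest higher run went from SYNPCC7002_G0016 to SYNPCC7002_G0026, 11 tags with a median log2 fold change of 7.05 and a range of 1.22 to 7.95. Its share of the summed signal was 0.0197% in replete, 2.82% in mild and 5.13% in severe limitation. Among the lower runs, that from SYNPCC7002_F0042 to SYNPCC7002_F0049, 8 tags, had median log2 fold changes of -0.82 in mild, -1.91 in strong and -3.58 in severe limitation. Across tags, which are not independent replicates, the correlation of log2 fold changes was 0.47 at a distance of 1 tag number and 0.04 at 10.

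On the log2 scale the tags with large rises had made more of their change in mild limitation than those with large falls, but this depended on scaling and on the log2 scale itself. The 80 tags at least 4-fold higher in severe limitation had a median of 80.7% of their log2 change in mild limitation, and the 67 tags at least 4-fold lower had 45.3%. In level rather than log2, the median share of the change reached in mild limitation was 58.8% for the rises and 64.1% for the falls, so the contrast is not seen there. The log2 gap of 35.4 percentage points gave p = 1e-04 in a permutation test over 10000 shuffles of direction across tags, the smallest they can give, but tags are not independent. With tags chosen again after each rescaling, the gap was 4.87 points without the 10 most abundant tags and -5.73 with all libraries at the same total. The contrast also depends on the level used to pick tags: among tags at least 4-fold changed in strong limitation, the median was 87.9% for 67 higher and 84.4% for 37 lower tags.

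Beside each count of calls, the splits of its 6 libraries are too few for a share under 0.05. The real split gave 2021, 1561 and 1200 calls for severe, strong and mild against replete, 516 for strong against mild and 1152 for severe against strong, and the highest of the other 9 splits gave 0 in each, so that 1 of 10 splits was as large. For the F test over the iron series, 1 of 100 splits of the 12 libraries, the real one, gave as many as 2381 calls, and the highest of the others gave 792, so chance assignment of libraries to levels is excluded at a share of 0.05.

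The count of called tags rose from mild to severe limitation, and so did depth. With all libraries thinned to the same effective depth, severe limitation still had 1.85 times as many calls against replete as mild, which argues against depth as the whole cause. The mean variance of log2 values was 0.0384 within the severe, 0.0255 within the strong, 0.0795 within the mild and 0.0790 within the replete libraries. The fit gives each tag 1 standard error for all levels, although their spread was unequal. In fits on each pair alone, 1957 tags passed in severe and 799 in mild against replete. The median absolute log2 fold change was 0.26 higher in severe than in mild limitation (0.21 to 0.28 with 1 library left out), which argues against spread as the whole cause. A larger response at lower iron remains as a hypothesis consistent with these tests, and other differences between the cultures, such as growth rate, were not tested.

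Series E was higher at every limited level, a pattern noticed in these data, and 3 explanations were set against this. Of 10000 lists of chromosomal tags matched on size and mean expression, 0 had a median as high as 0.93 in severe limitation, which argues against low expression. Relative to series A the median was still 0.89, so scaling between libraries does not account for it. If the whole plasmid moved by about 1 amount and its tags did not change otherwise, they would vary less than matched chromosomal tags. However, 53.57% of the matched lists had a standard deviation as small, so a shared shift alone does not describe the series. A shift shared by the series, as a change in copy number might give, with changes of single tags on top of it stays open. The standard deviation cannot count against it, since a constant added to every tag leaves it the same. Within the replete level the median of series E was -0.23, 0.09 and 0.19 in replicates A, B and C. The medians of the other plasmid series rose in the same order and that of series A fell. In severe limitation 31 of its 37 tags were above 0, while the camera call was lost with an estimated correlation (adjusted p = 0.41).

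Series F was lower in severe than in strong limitation, a pattern also noticed in these data. Of 10000 matched chromosomal lists, 0 had a median as low as -0.51. Relative to series A the median was -0.57, and it stayed at -0.23 when all libraries were rescaled to the same total, so neither low expression nor scaling accounts for it. A shift of all its tags by about 1 amount and nothing else is not favoured either, since 98.50% of the matched lists had a standard deviation as small as that of series F. A shift with changes of single tags on top stays open, as the standard deviation cannot count against it. The camera call was lost with an estimated correlation (adjusted p = 0.21), and a regulated response of groups of neighbouring tags on this plasmid remains a hypothesis that was not tested apart from the iron level.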
